A study of Homo sapiens with 8 samples.

How the data were processed

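RNA sequencing libraries were made from total RNA, treated with DNase, of the parental line (HEL92.1.7) and its P/R derivative, each untreated or exposed to 1000 nM OTX015 for 8 hours, with 2 libraries in each of 4 groups. The labels call the replicates biologic and independently treated. Whether messenger RNA was selected by its poly(A) tail, and whether strand was kept, is not given in the sources used here, which matters for histone genes, whose main transcripts lack the tail, and for genes that overlap on opposite strands.

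The authors deposited 1 table of 19718 coding genes by 8 libraries, with Ensembl identifiers and symbols, and its values are taken to be FPKM (fragments per kilobase of transcript, scaled to library size). The header names no unit. It was inferred from the values, which are never negative and not whole, and from the tools named: TopHat2 2.0, Cufflinks 2.0 and the genome build hg19, per the submitters' processing notes. The role and settings of each tool, the annotation and any filter are not given in the sources used here. The deposited FPKM values are quantile normalized across libraries, as shown by the values: at a mean of 1 FPKM or more, the sorted values of any 2 libraries differ by at most 0.136%, and every library sums to 678133. Of the symbols, 28 had been turned into bare numbers, and these genes were named through their Ensembl identifiers.

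The sequencing depth cannot be recovered from such values, so no interval for counting error is given. Quantile normalization also removes any global change in RNA content and gives genes of equal rank equal values, which makes the spread of some abundant genes 0. Genes with near-identical copies (histone, MAGEA, GAGE12, globin, HSPA1 and SMIM11 families) are uncertain, because the reads may have been divided between copies.

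Genes entered the tests with at least 1 FPKM in at least 2 of 8 libraries, which left 11255. Values were transformed to log2(FPKM + 1), and fold changes are on this scale, which understates the change of low genes; ratios printed as folds are ratios of mean FPKM. A linear model with 4 group means was fitted in limma 3.58.1 (R 4.3.3; lmFit, then eBayes with a variance trend), with 4 residual and 5.23 prior degrees of freedom, and p-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. The 5 contrasts were OTX015 against untreated in each line, P/R against parental cells untreated and under OTX015, and the difference in OTX015 response between the lines. All adjusted p-values printed for single genes come from this limma fit. Tests are two-sided.

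Before the data were examined, 26 gene lists were fixed. They cover the study axis, BET proteins and P-TEFb, polyadenylated histone genes, BET inhibitor-sensitive leukaemia genes, MYC targets, WNT targets and components, JAK-STAT, the BCL2 family, erythroid, megakaryocyte, monocyte and granulocyte, and stem and progenitor genes. The others cover S phase, mitosis, CDK inhibitors and p53, cholesterol, NF-kB, interferon, ATF4 and the unfolded protein response, heat shock, drug efflux, lymphocyte, epithelial and stromal, ribosomal protein and reference genes. Each was tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 26 lists of a contrast, and again with an estimated correlation. Only the MYC target calls under OTX015, in both lines, held with an estimated correlation. The design, the alternatives and the rule for named genes were also fixed then. The rule names the study axis and HEXIM1, the 8 largest rises and 8 largest falls that passed, with a group mean of at least 5 FPKM and no overlap of replicates (5 and 5 for the comparison under OTX015 and for the difference in response), and up to 4 members of each called list.

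The alternatives were pseudocounts of 0.1 and 5, no filter, a mean of at least 5 FPKM, no variance trend, median centring, a fit of only the groups compared, a replicate block, a log2 fold of at least 1, and leaving out each library in turn. A crossed block and the removal of a local median along the chromosome were added after the data were seen. Runs of neighbouring genes were sought with a running median over 41 tested genes within a chromosome, as at least 40 genes in a row beyond 0.3 on the log2 scale. The gene order comes from a GRCh38 annotation (GENCODE) matched by Ensembl identifier, which placed 11210 genes. Because the table was made on hg19, no coordinates are printed. The end rule of the running median was changed after a first version gave artefacts at chromosome ends in shuffled data.

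The tests were tested on simulated data. For OTX015 in parental cells, with 11039 simulated genes, the fit recovered 100% of changes of 1 and 96% of changes of 0.5 on the log2 scale, with 12 false calls. For the difference in response, it recovered 100% and 65%. The changes were planted only in genes above a level of 5 FPKM, so these rates do not cover lower genes. Nor need they hold for genes with a large spread. In the data themselves, GAGE12B differed in response by -4.11 and did not pass limma's test (adjusted p = 0.223). The shifted list and the planted run were recovered with 0 other lists and 0 other runs called. The simulated genes varied independently of each other, so this cannot show how often lists or runs are falsely called when genes vary together. Groups of 2 allow neither a permutation p under 0.333 nor an outlier test, and neither was run.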

Results

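Messenger RNA levels were measured in HEL92.1.7 cells, an erythroleukaemia line that serves as a model of secondary acute myeloid leukaemia, and in a derivative of that line, HEL OTX P/R, which persisted through and became resistant to OTX015. OTX015 (birabresib) is a small molecule that blocks the bromodomains of the BET protein family. Each line was sampled untreated and after 8 hours in 1000 nM OTX015, with 2 biological replicates per group and 8 libraries in all. The lines are called parental and P/R below. The table lists 19718 coding genes in quantile-normalized FPKM, and 11255 of them reached 1 FPKM in at least 2 libraries and were tested. Every library totals 678133 FPKM because of the normalization, so the sequencing depth is unknown and no counting error can be given. Replicates correlated at r = 0.996 to 0.997 across genes, against 0.959 to 0.985 between libraries of different groups; genes are not independent replicates.

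The title of the series names a β-catenin, TCF7L2, JMJD6 and MYC axis in resistance to BET inhibitors, so these genes were read out first. CTNNB1, the gene of β-catenin, rose under OTX015 in parental cells from 83.1 ± 3.44 to 125 ± 1.02 FPKM (mean ± SD, n = 2, as for all such values), and in P/R cells from 85 ± 0.474 to 116 ± 1.14 FPKM. JMJD6, which encodes an arginine demethylase and lysine hydroxylase, fell from 30.8 ± 0.818 to 18.5 ± 0.866 FPKM in parental cells and from 35.2 ± 1.47 to 24.2 ± 1.09 FPKM in P/R cells. MYC, which encodes the growth-promoting transcription factor, fell from 501 to 434 FPKM in parental cells and from 461 to 389.8 FPKM in P/R cells. TCF7L2, the gene of a transcription factor that partners β-catenin, fell in P/R cells from 7.85 ± 0.762 to 4.92 ± 0.414 FPKM. In parental cells its levels were 6.42 ± 0.378 and 5.35 ± 0.478 FPKM, a difference that did not pass the test (adjusted p = 0.104). HEXIM1, an inhibitor of the elongation factor P-TEFb whose transcript rises when BET proteins are blocked, rose 3.3-fold in parental cells and 2.8-fold in P/R cells.

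**Figure D1:**
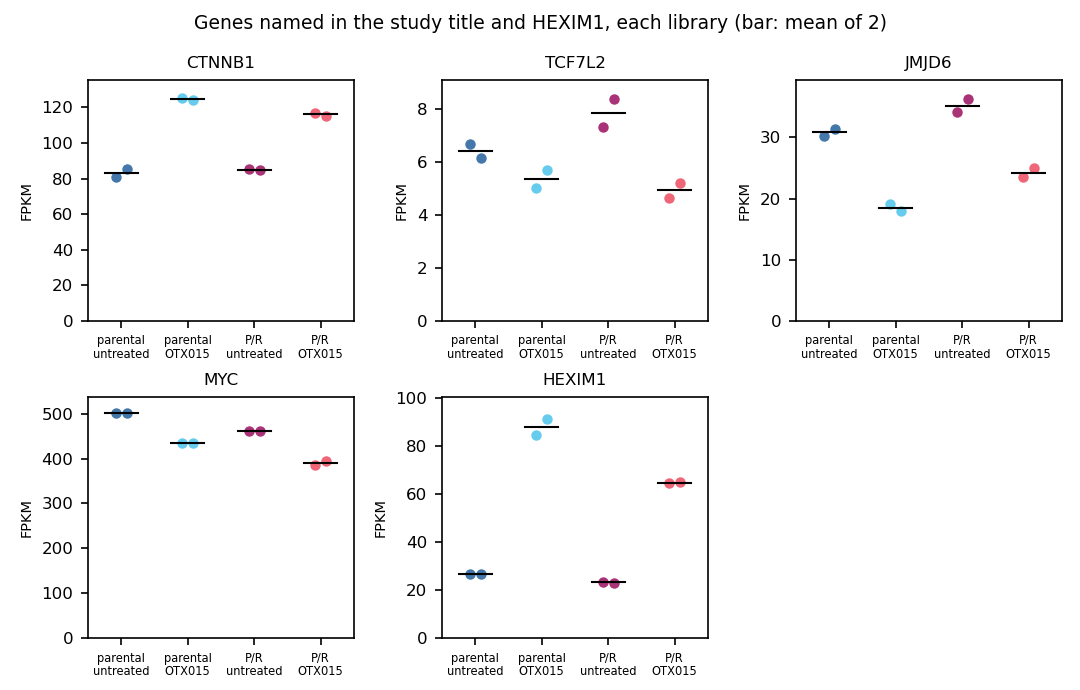
FPKM of CTNNB1, TCF7L2, JMJD6, MYC and HEXIM1 in each library, with 1 point per library and a bar at the mean of the 2 replicates of each group. HEXIM1 went from 26.6 to 87.9 FPKM in parental cells and from 23.1 to 64.6 FPKM in P/R cells.

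Untreated P/R cells had 0.12 lower log2 MYC (adjusted p = 0.0292) and lower HEXIM1 (log2 difference -0.20, adjusted p = 0.0283). Both calls were lost when any one of the 4 untreated libraries was left out. Under OTX015, P/R cells had more JMJD6 (log2 difference 0.37, adjusted p = 0.00316), less MYC (-0.16, adjusted p = 0.00876) and less HEXIM1 (-0.44, adjusted p = 0.000391) than parental cells. The MYC call under OTX015 was lost without the variance trend. CTNNB1 and TCF7L2 passed in neither line comparison, with adjusted p = 0.661 and 0.123 in untreated cells and 0.135 and 0.553 under OTX015. The difference in OTX015 response between the lines passed for none of the 5 genes, with adjusted p from 0.36 for HEXIM1 to 0.874 for MYC. As a list of 4, the study axis was called in no comparison. In parental cells 1 member rose, 2 fell and 1 did not pass (adjusted p = 0.412 for the list), with the same counts adjusted over the list alone. The MYC values are means over a rank that quantile normalization assigns to every library, so replicates of equal rank have identical values and the spread of this gene is understated.

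The first comparison asks what 8 hours of OTX015 did in parental cells. Most of the largest rises were of histone genes. HIST1H4H rose 12-fold, from 1.23 ± 0.103 to 14.8 ± 2.86 FPKM. HIST2H2BE rose 8.95-fold, and HIST1H2AD and HIST1H3D rose from below 1 FPKM to 10.3 ± 0.771 and 5.46 ± 0.012 FPKM. HIST2H4A and HIST2H4B also rose, but these copies are near identical and reads could be assigned to either. Outside the histones, IRF7, an interferon regulatory factor, rose 6.51-fold to 62.7 ± 4.3 FPKM, and PLCD3, a phospholipase C, rose 7.09-fold to 11.6 ± 0.702 FPKM. IL1B, which encodes the inflammatory cytokine interleukin 1β, fell from 25.7 ± 1.38 to 1.09 ± 0.008 FPKM (log2 change -3.68). KCNH2, a potassium channel gene, fell from 79.3 ± 1.26 to 8.49 ± 0.53 FPKM, and APLNR, the apelin receptor, from 15.9 ± 0.159 to 1.25 ± 0.0673 FPKM. GPR85, LRFN4, CSF1 (the macrophage colony-stimulating factor), ITLN2 and WNT5B fell by 2.74, 2.58, 2.58, 2.48 and 2.37 on the log2 scale.

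Of the 19 polyadenylated histone genes, 17 rose, 0 fell and 2 did not pass, and 17 rose adjusted over the list alone (median log2 change 1.76, adjusted p = 5.39e-13; adjusted p = 0.0964 with an estimated correlation). HIST1H1C went from 28.4 ± 1.24 to 102 ± 3.94 FPKM, H1F0 from 141 ± 2.42 to 403 ± 9.36 FPKM and HIST1H2BK from 65.9 ± 2.71 to 226 ± 25.4 FPKM. Reads of HIST2H2AA3, up 5.04-fold, may be shared with its twin HIST2H2AA4. Among BET proteins and P-TEFb components, 12 of 20 rose, 1 fell and 7 did not pass, with the same counts of calls adjusted over the list alone (adjusted p = 0.00167; adjusted p = 0.187 with an estimated correlation). BRD2 rose 2.38-fold, AFF1 1.72-fold and CDK7 1.62-fold, and LARP7, which holds P-TEFb in its inactive complex, fell. Among CDK inhibitors and p53 targets, 12 of 19 rose, 2 fell and 5 did not pass, the same as adjusted over the list alone (adjusted p = 0.000761; adjusted p = 0.133 with an estimated correlation). BTG2, TP53I3, GADD45A and CDKN2C rose 2.29-, 3.09-, 1.66- and 1.53-fold, while GDF15 and PLK3 fell. S phase and E2F targets had 18 of 40 members that rose, 7 that fell and 15 that did not pass, with the same calls adjusted over the list alone (adjusted p = 0.049973; adjusted p = 0.133 with an estimated correlation). RRM2, a subunit of ribonucleotide reductase, rose 1.85-fold, TK1 1.55-fold, RFC5 1.61-fold and SLBP 1.32-fold. The call of this list held in only 5 of 15 other settings, where its adjusted p ran from 0.0312 to 0.0782.

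MYC targets, mostly genes of ribosome assembly and nucleotide supply, fell in 43 of 59 cases, rose in 4 and did not pass in 12. Adjusted over the list alone 44 fell and 5 rose. The list had a median log2 change of -0.34 (adjusted p = 4.99e-09), and its call held with an estimated correlation (adjusted p = 0.0451). MRTO4, SLC19A1, DCTPP1 and PPAN were at 0.575, 0.54, 0.634 and 0.629 of their untreated levels. BET inhibitor-sensitive leukaemia genes fell in 15 of 22 cases, rose in 2 and did not pass in 5, the same as adjusted over the list alone (adjusted p = 0.000119; adjusted p = 0.133 with an estimated correlation). LMO2 fell from 61.1 ± 7 to 14.1 ± 0.584 FPKM, PIM1 from 227 ± 7.72 to 78.9 ± 0.742 FPKM, SPI1 from 110.1 ± 7.47 to 36.4 ± 1.19 FPKM and FOSL1 from 31.1 ± 2.78 to 9.09 ± 0.395 FPKM. Stem and progenitor genes fell in 10 of 13 cases, rose in 1 and did not pass in 2, the same as adjusted over the list alone (adjusted p = 0.000717; adjusted p = 0.133 with an estimated correlation). MYB went to 0.505 and MSI2 to 0.569 of the untreated level, whereas CD34 and ANGPT1 fell from 0.973 and 1.83 FPKM to 0.0449 and 0.143 FPKM.

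Megakaryocyte genes fell in 16 of 21 cases, rose in 3 and did not pass in 2, the same as adjusted over the list alone (median log2 change -0.64, adjusted p = 8.25e-05; adjusted p = 0.133 with an estimated correlation). LAT, an adaptor of platelets and T cells, fell from 232 ± 6.56 to 69 ± 0.289 FPKM, PLEK (pleckstrin) from 299.7 ± 4.71 to 129 ± 5.46 FPKM, and the platelet receptor genes GP6 and GP1BA from 25.3 ± 0.0122 to 6.08 ± 0.274 and from 30.6 ± 0.982 to 13.3 ± 0.923 FPKM. ITGB3, SERPINE2 and ZFPM1 rose. Erythroid genes fell in 17 of 34 cases, rose in 9 and did not pass in 8, the same as adjusted over the list alone (adjusted p = 0.0272; adjusted p = 0.133 with an estimated correlation). EPB42, GYPC and HEMGN, genes of the red cell membrane and of erythroid differentiation, were at 0.323, 0.59 and 0.296 of their untreated levels, while CPOX and ALAD of haem synthesis rose. Monocyte and granulocyte genes fell in 8 of 13 cases, rose in 2 and did not pass in 3; adjusted over the list alone 9 fell and 2 rose (adjusted p = 0.0112; adjusted p = 0.133 with an estimated correlation). The call was lost without the filter on low values, at an adjusted p of 0.0608. The members that fell most were SPI1, CD36, LST1 and FCGR2A, of which CD36 and FCGR2A are also platelet genes. Lymphocyte genes fell in 4 of 6 cases and did not pass in 2, and 5 fell adjusted over the list alone (adjusted p = 0.00279; adjusted p = 0.133 with an estimated correlation). The 4 were CD2, a T and NK cell adhesion molecule, PRF1, the pore former of cytotoxic cells, and CD79A and CD79B, chains of the B cell receptor. None of them exceeded 8.75 FPKM in any group mean.

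ATF4 and unfolded protein response genes fell in 15 of 25 cases, rose in 5 and did not pass in 5, the same as adjusted over the list alone (adjusted p = 0.000843; adjusted p = 0.133 with an estimated correlation). The chaperone genes of the endoplasmic reticulum HSPA5 and HSP90B1 fell from 261 ± 3.63 to 66.7 ± 0.325 and from 318 ± 3.12 to 140.3 ± 7.11 FPKM. SDF2L1 and HERPUD1 were at 0.272 and 0.249 of their untreated levels, while ATF3 and SESN2 rose. Heat shock genes fell in 9 of 14 cases, rose in 0 and did not pass in 5, and 10 fell adjusted over the list alone (adjusted p = 0.000645; adjusted p = 0.131 with an estimated correlation). HSPH1 went to 0.529, HSPE1 to 0.692 and HSPA8 to 0.738 of the untreated level; HSPA1B, at 0.611, shares sequence with HSPA1A. JAK-STAT feedback genes and targets fell in 11 of 21 cases, rose in 3 and did not pass in 7; adjusted over the list alone 11 fell and 4 rose (adjusted p = 0.0272; adjusted p = 0.133 with an estimated correlation). PIM1, STAT5A, CISH and BCL2L1 fell by 1.51, 0.84, 0.87 and 0.47 on the log2 scale. This call was lost without parental OTX015 replicate 1, at an adjusted p of 0.0544.

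Other lists were not called in parental cells. WNT target genes rose in 3, fell in 5 and did not pass in 7 of 15 cases (adjusted p = 0.454), and WNT pathway components rose in 11, fell in 5 and did not pass in 14 of 30 (adjusted p = 0.504, median log2 change 0.06 and mean -0.03). LEF1 went from 19.5 ± 0.0636 to 12.3 ± 0.444 FPKM, and its fall passed the test. NF-kB targets rose in 2 and fell in 8 of 20 cases (adjusted p = 0.159), interferon-stimulated genes rose in 6 and fell in 13 of 24 (adjusted p = 0.178), and mitotic genes rose in 10 and fell in 5 of 32 (adjusted p = 0.176). The BCL2 family and IAPs rose in 4 and fell in 3 of 14 cases (adjusted p = 0.785), and drug efflux and metabolism genes rose in 5 and fell in 3 of 13 (adjusted p = 0.504). Cholesterol genes rose in 7 and fell in 9 of 24 cases (adjusted p = 0.862, median -0.03 and mean 0.01). Epithelial and stromal genes fell in 2 of 4 cases (adjusted p = 0.0826), cytosolic ribosomal protein genes rose in 5 and fell in 9 of 42 (adjusted p = 0.315), and commonly used reference genes rose in 5 and fell in 5 of 16 (adjusted p = 0.785). In each of these 11 lists the remaining tested members did not pass. Adjusted over the list alone the same numbers rose and fell, except interferon-stimulated genes (6 and 14), cholesterol genes (8 and 9), ribosomal protein genes (2 and 7) and reference genes (6 and 5).

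In this comparison 5667 genes passed limma's moderated test at an adjusted p under 0.05, 2890 higher and 2777 lower, and 186 of the former and 300 of the latter by at least 1 on the log2 scale. Quantile normalization gives every library the same distribution, so a general rise or fall of transcription under a BET inhibitor would not be seen and the balance of higher and lower genes is in part set by it. With 2 libraries per group the smallest two-sided exact permutation p is 0.333, so every p-value here rests on the model that shares the spread among genes and groups.

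The same treatment in P/R cells asks which part of the BET inhibitor response the resistant derivative kept. The histone genes again rose most. HIST2H4A rose from 4.01 ± 0.0953 to 49.5 ± 0.919 FPKM, HIST1H3H from 2.79 ± 0.812 to 24.2 ± 2.15 FPKM and HIST1H2BJ from 15.7 ± 1.33 to 104 ± 2.04 FPKM. HIST2H4B, HIST1H2BG, HIST2H2BE and HIST1H2AE rose by 3.07, 2.62, 2.51 and 2.47 on the log2 scale, and DHRS2, a dehydrogenase gene, rose 6.79-fold. IL1B fell from 28.6 ± 2.8 to 2.01 ± 1.65 FPKM and KCNH2 from 68.5 ± 1.85 to 10.2 ± 2.99 FPKM. ANGPT1, the gene of angiopoietin 1, fell from 8.02 ± 0.712 to 0.352 ± 0.262 FPKM, APLNR from 22.3 ± 0.781 to 3.73 ± 1.3 FPKM and ITLN2 from 31.3 ± 0.472 to 6.15 ± 1.25 FPKM. GRIK4 and SMIM11B also fell, though the replicates of GRIK4 were far apart (46.2 ± 17.8 FPKM untreated) and SMIM11B has a near-identical copy. GAGE12B, a member of a family of near-identical cancer-testis genes, read 4.74 and 30.3 FPKM in the untreated P/R replicates and was listed at 0 in both treated ones.

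**Figure D2:**
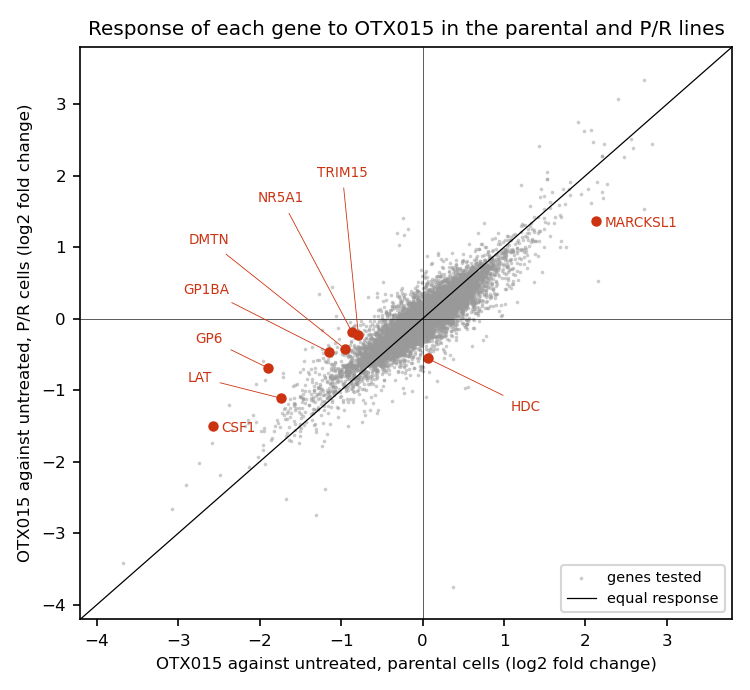
Log2 fold change of each tested gene under OTX015 in parental cells (horizontal) and in P/R cells (vertical), on the log2(FPKM + 1) scale; the diagonal marks an equal response. The 9 genes whose response differed between the lines are named, and the fold changes correlate at r = 0.891 across the 11255 genes.

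Of 26 lists, 11 were called in P/R cells, all in the direction they had in parental cells. Histone genes rose in 18 of 19 cases and did not pass in 1, with 18 adjusted over the list alone (median log2 change 1.73, adjusted p = 3.08e-15; adjusted p = 0.0723 with an estimated correlation); HIST1H1C went from 154 ± 0.834 to 514 ± 2 FPKM and H1F0 from 202 ± 2.42 to 516 ± 15.9 FPKM. MYC targets fell in 40 of 59 cases, rose in 3 and did not pass in 16, and adjusted over the list alone 42 fell and 4 rose (adjusted p = 8.24e-10). This call held with an estimated correlation (adjusted p = 0.0383), and MRTO4, SLC19A1, HSPE1 and PPAN were at 0.646, 0.607, 0.659 and 0.658 of their untreated levels. BET inhibitor-sensitive leukaemia genes fell in 16 of 22 cases and did not pass in 6; adjusted over the list alone 16 fell and 1 rose (adjusted p = 2.82e-05; adjusted p = 0.153 with an estimated correlation). PIM1 and MYB were at 0.348 and 0.403 of their untreated levels, and SPI1 and LMO2 at 0.408 and 0.357. Stem and progenitor genes fell in 9 of 13 cases and did not pass in 4; adjusted over the list alone 11 fell and 1 rose (adjusted p = 0.000192; adjusted p = 0.153 with an estimated correlation). CD34 went from 2.75 ± 0.0894 to 0.322 ± 0.0364 FPKM and MSI2 from 18 ± 0.41 to 12 ± 0.604 FPKM.

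Megakaryocyte genes fell in 14 of 21 cases, rose in 3 and did not pass in 4, the same as adjusted over the list alone (median log2 change -0.47, adjusted p = 0.000284; adjusted p = 0.171 with an estimated correlation). PLEK, LAT, GP5 and SELP were at 0.425, 0.462, 0.108 and 0.291 of their untreated levels, GP5 from only 3.1 FPKM. Monocyte and granulocyte genes fell in 8 of 13 cases and did not pass in 5, the same as adjusted over the list alone (adjusted p = 0.00431; adjusted p = 0.151 with an estimated correlation), led by SPI1, LST1, CD36 and FCGR2A. ATF4 and unfolded protein response genes fell in 15 of 25 cases, rose in 4 and did not pass in 6, the same as adjusted over the list alone (adjusted p = 0.000142; adjusted p = 0.153 with an estimated correlation). HSPA5 went from 269 ± 7.49 to 78 ± 5.6 FPKM, and HSP90B1, SDF2L1 and PDIA4 were at 0.463, 0.312 and 0.555 of their untreated levels. Heat shock genes fell in 9 of 14 cases and did not pass in 5, with 10 adjusted over the list alone (adjusted p = 0.000142; adjusted p = 0.0962 with an estimated correlation); HSPH1, HSPA8 and HSPD1 were at 0.572, 0.819 and 0.773.

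CDK inhibitors and p53 targets rose in 11 of 19 cases, fell in 2 and did not pass in 6, the same as adjusted over the list alone (adjusted p = 0.000284; adjusted p = 0.153 with an estimated correlation). BTG2, TP53I3, CDKN2C and GADD45A rose 1.95-, 2.98-, 1.54- and 1.51-fold. S phase and E2F targets rose in 21 of 40 cases, fell in 5 and did not pass in 14; adjusted over the list alone 21 rose and 6 fell (adjusted p = 0.00431; adjusted p = 0.134 with an estimated correlation). RRM2, TK1, RFC5 and SLBP rose 1.87-, 1.62-, 1.47- and 1.29-fold. BET proteins and P-TEFb components rose in 10 of 20 cases, fell in 2 and did not pass in 8, the same as adjusted over the list alone (adjusted p = 0.0145; adjusted p = 0.307 with an estimated correlation). BRD2, MEPCE and AFF1 rose 1.97-, 1.27- and 1.48-fold, and HEXIM2 and LARP7 fell. The JAK-STAT, lymphocyte and erythroid lists, called in parental cells, had adjusted p = 0.0508, 0.0573 and 0.122 here. Median and mean differed in sign for the interferon-stimulated and cholesterol lists, neither of them called.

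In P/R cells 4981 genes passed, 2531 higher and 2450 lower, of which 117 and 197 by at least 1 on the log2 scale. The responses of the lines, which share no library, correlated across genes at Pearson r = 0.891 and Spearman rho = 0.868. The genes called higher in both lines numbered 2089, against 649.9 for independent lists, and those called lower in both 2051, against 604.5; 11 genes, 4 of them higher and 7 lower in parental cells, were called in opposite directions. After removal of the replicate noise, the P/R response had 0.887 times the spread of the parental response and a slope of 0.861 on it. This slope is a description without a test.

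Whether a gene's response differed between the lines was tested directly. The platelet collagen receptor gene GP6 fell less in P/R cells, from 47.8 ± 1.15 to 29.2 ± 1.81 FPKM against 25.3 to 6.08 FPKM in parental cells (difference in log2 response 1.20, SE 0.10, adjusted p = 0.00412). MARCKSL1, which encodes an actin-binding protein, rose less, from 60.6 ± 0.298 to 158 ± 3.32 FPKM against 41.5 ± 0.134 to 185 ± 6.85 FPKM (difference -0.76, SE 0.065, adjusted p = 0.00412). CSF1, NR5A1, GP1BA and LAT fell less in P/R cells, with differences of 1.08, 0.69, 0.69 and 0.62, but these calls were lost in 12, 9, 12 and 11 of 15 other settings. HDC, the histidine decarboxylase gene, went from 403 ± 31.6 to 421 ± 13.6 FPKM in parental cells and from 255 ± 11.2 to 173 ± 2.87 FPKM in P/R cells (difference -0.62, adjusted p = 0.0478), a call lost in 11 of 15 other settings. TRIM15 and DMTN, with differences of 0.56 and 0.54, complete the 9 genes that passed; they fall outside the rule for named genes and were added after their values were seen.

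As a list, megakaryocyte genes fell less in P/R cells, with 3 of 21 members passing in that direction, 18 not passing and 5 adjusted over the list alone (median difference 0.12, adjusted p = 0.00412; adjusted p = 0.623 with an estimated correlation). TUBB1, a β-tubulin of platelets, had a difference of 0.48 that did not pass. The list's call was lost with a pseudocount of 5 (median difference 0.0589, adjusted p = 0.102), without the filter on low values (0.0133, adjusted p = 0.136) and without P/R OTX015 replicate 1 (0.0344, adjusted p = 0.113). Lymphocyte genes differed in the same direction with 0 of 6 members passing and 3 adjusted over the list alone (median 0.40, adjusted p = 0.000582; adjusted p = 0.623 with an estimated correlation); PRF1, CD79B and CD79A had differences of 1.09, 0.50 and 0.33. That of CD2 (0.40) comes from the pseudocount at unequal low levels, since its FPKM fell to 0.279 of the untreated level in parental and 0.283 in P/R cells, and it was 0.0941 with a pseudocount of 0.1. The list of BET proteins and P-TEFb components had a negative difference with 0 of 20 members passing, also adjusted over the list alone (median difference -0.12, with medians of 0.24 and 0.23 under OTX015 in parental and P/R cells, adjusted p = 0.0288; adjusted p = 0.623 with an estimated correlation). HEXIM1, CDK7, BRD2 and HEXIM2 had differences of -0.24, -0.40, -0.28 and -0.36. This call held in 8 of 15 other settings. Median and mean, or either of them and the test, differed in sign for the heat shock, histone, WNT component, monocyte, NF-kB, ATF4, BCL2, mitotic and drug efflux lists, none of them called.

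The 9 genes passing limma's test, 7 higher and 2 lower, compare with 1080 genes at an unadjusted p under 0.05, where 562.8 would be expected by chance. The number ranged from 0, without untreated P/R replicate 2, to 29, with a pseudocount of 5. It was 3 and 2 without untreated parental replicates 1 and 2, 5 and 2 without the OTX015-treated parental replicates, 2 without untreated P/R replicate 1 and 2 without OTX015-treated P/R replicate 1.

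The untreated lines were compared to ask what sets the derivative apart before any renewed exposure. Genes with more transcript in P/R cells included many platelet and megakaryocyte genes, some histone genes, the keratins KRT8 and KRT18 and some MAGE family genes. Several mast cell genes had less, and the MAGE and mast cell groups were named only after the values were seen. PF4, platelet factor 4, stood at 48.9 ± 2.14 FPKM in P/R and 2.33 ± 0.471 FPKM in parental cells (21-fold, log2 difference 3.91). NNMT, which methylates nicotinamide, stood at 10.7 ± 0.146 against 0.353 ± 0.194 FPKM, ZFPM2, a cofactor of GATA factors, at 13.3 ± 0.606 against 1.27 ± 0.151 FPKM, and MYLK, myosin light chain kinase, at 31.8 ± 1.28 against 5.63 ± 0.136 FPKM. C1orf116 was 6.56-fold higher. MAGEA2B, at 6.09 ± 0.899 against 0.335 ± 0.157 FPKM, cannot be separated from its copy MAGEA2, and the call of GAGE12B, whose P/R replicates were far apart, was lost without the filter or untreated parental replicate 2. GALNS, a lysosomal sulfatase gene, was lower in P/R cells, at 7.58 ± 0.181 against 70.8 ± 2.07 FPKM. APOE (apolipoprotein E) stood at 4.06 ± 0.313 against 26.6 ± 2.69 FPKM, AQP1 (a water channel) at 2.13 ± 0.0961 against 13.4 ± 0.0212 FPKM, and KIT (the stem cell factor receptor) at 2.09 ± 0.178 against 12.3 ± 1.46 FPKM. CPA3 and PRG2, granule proteins of mast cells and eosinophils, and STXBP6 were at 0.123, 0.182 and 0.16 of the parental level. H2AFJ read 5.16 and 5.67 FPKM in the parental replicates and was listed at 0 in both P/R replicates.

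Megakaryocyte genes were higher in P/R cells in 17 of 21 cases, lower in 1 and did not pass in 3; adjusted over the list alone 17 were higher and 2 lower (median log2 difference 0.68, adjusted p = 2e-11; adjusted p = 0.141 with an estimated correlation). GP1BA stood at 69.2 ± 2.08 against 30.6 ± 0.982 FPKM, ITGB3 at 73.7 ± 2.37 against 40.8 ± 0.904 FPKM and THBS1 at 56 ± 1.24 against 18.8 ± 1.52 FPKM. GP1BA lies in the higher stretch of chromosome 17 described further on, and its log2 difference of 1.15 was 0.595 with the local median removed. ITGA2B, the partner chain of ITGB3 in the fibrinogen receptor, was the member that was lower (log2 difference -0.27). Histone genes were higher in 14 of 19 cases, lower in 1 and did not pass in 4; adjusted over the list alone 15 were higher and 1 lower (median 0.66, adjusted p = 1.44e-08; adjusted p = 0.141 with an estimated correlation). HIST1H1C, HIST1H2BK and HIST1H2AC were 5.43-, 4.99- and 4.04-fold higher, HIST2H2AA3 2.51-fold, and the lower one was H2AFJ. The epithelial and stromal list had 4 tested members of 17, all higher, also adjusted over the list alone (median 1.33, adjusted p = 2.76e-05; adjusted p = 0.198 with an estimated correlation). They were the keratins KRT18 (75 ± 0.845 against 15 ± 1.83 FPKM) and KRT8 (15.8 ± 0.221 against 3.93 ± 0.251 FPKM), the endothelial cadherin CDH5 (2.63 ± 0.209 against 0.963 ± 0.106 FPKM) and PECAM1 (13.4 ± 0.0506 against 10.4 ± 0.422 FPKM), an adhesion molecule of endothelium and platelets. The call of PECAM1 was lost without untreated parental replicate 2 or either untreated P/R replicate.

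Monocyte and granulocyte genes were higher in 4 of 13 cases and did not pass in 9, with 5 adjusted over the list alone (median 0.02, mean 0.30, adjusted p = 0.0368; adjusted p = 0.205 with an estimated correlation). The 4 were CD68, LST1, CD4 and CEBPD, of which CD68 lies in a stretch of chromosome 17 described further on. The call held in 10 of 15 other settings, with adjusted p from 0.0128 to 0.16. It was lost without the filter, at a mean of at least 5 FPKM, without the variance trend, and without untreated parental replicate 1 or untreated P/R replicate 2. Lymphocyte genes were lower in 4 of 6 cases and did not pass in 2; adjusted over the list alone 5 were lower and 1 higher (median -1.11, adjusted p = 0.00161; adjusted p = 0.198 with an estimated correlation). CD2, CD79A, PRF1 and CD79B were at 0.329, 0.288, 0.231 and 0.434 of the parental level. Cytosolic ribosomal protein genes were lower in 13 of 42 cases and did not pass in 29, with 14 adjusted over the list alone (median -0.05, adjusted p = 0.00132; adjusted p = 0.337 with an estimated correlation). RPL27, RPL19, RPL23 and RPS3 were at 0.677, 0.69, 0.658 and 0.864 of the parental level, and the first 3 lie in the lower stretch of chromosome 17. S phase and E2F targets were lower in 9 of 40 cases and did not pass in 31, with 8 adjusted over the list alone (median -0.10, adjusted p = 0.00252; adjusted p = 0.141 with an estimated correlation). CDC6, MCM3, RFC4 and CCNE1 were at 0.633, 0.834, 0.709 and 0.493, of which CDC6 and RFC4 lie in lower stretches. MYC targets were lower in 17 of 59 cases, higher in 1 and did not pass in 41; adjusted over the list alone 19 were lower and 1 higher (median -0.10, adjusted p = 0.0131; adjusted p = 0.166 with an estimated correlation). IPO4, TMEM97, UNG and RRP9 were at 0.627, 0.473, 0.802 and 0.808, of which IPO4 and TMEM97 lie in lower stretches. The other 18 lists were not called, and for the BET inhibitor-sensitive, JAK-STAT and stem and progenitor lists median, mean and test differed in sign.

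**Figure D3:**
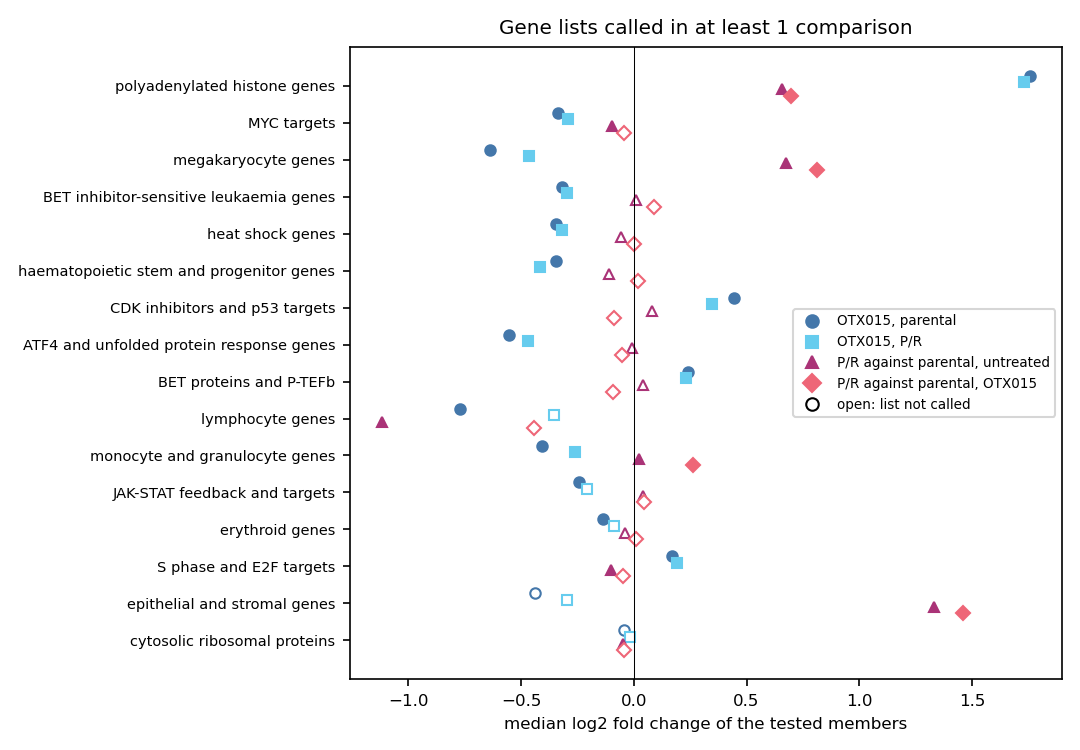
Median log2 fold change of the tested members of each list called in at least 1 comparison, for OTX015 in each line and for P/R against parental cells untreated and under OTX015; filled symbols mark called lists. Megakaryocyte genes lie at -0.64 and -0.47 under OTX015 and at 0.68 and 0.81 in P/R against parental cells.

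Part of the difference between the lines lay in 4 stretches of neighbouring genes. On chromosome 3, 85 tested genes from ACTL6A to RPL35A had a median log2 difference of -0.40, and on chromosome 14, 92 genes from TTC5 to SPTSSA had a median of -0.53. On chromosome 17, 203 genes from C17orf97 to DHRS7B were higher, with a median of 0.52, and 188 genes from LGALS9 to UBTF lower, with a median of -0.52. Of these 568 genes 456 (80.3%) were called between the untreated lines, against 20.4% of the other genes, and the 456 made up 17.4% of the called genes with a known position. Because the stretches were chosen by these same fold changes, a high share of calls in them follows from the choice and is no separate evidence. The same stretches had medians of -0.48, -0.47, 0.53 and -0.53 under OTX015. Named genes in them include CD68, GP1BA, GP5, STAT5A, RPL19, RPL23, RPL27, CDC6, RFC4, IPO4, TMEM97, STXBP6 and DHRS2. With the local median removed, an analysis added after the stretches were seen, the calls of HEXIM1, RPL27, RPL19, RPL23, CDC6, RFC4 and IPO4 between untreated lines and that of CD68 under OTX015 were lost. The search for stretches was itself added after the data were seen.

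**Figure D4:**
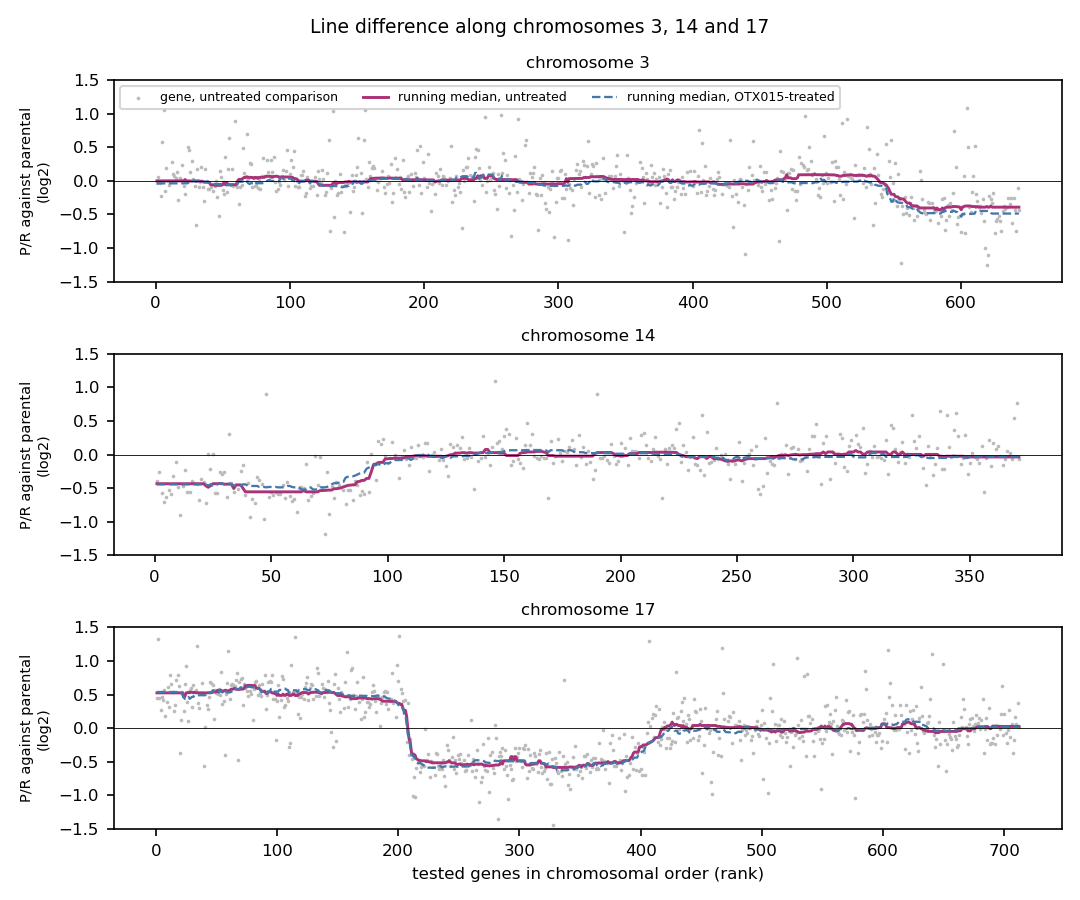
Log2 difference between P/R and parental cells for tested genes in their order along chromosomes 3, 14 and 17; points are genes in untreated cells and lines are running medians over 41 genes, solid for untreated and dashed for OTX015-treated cells. On chromosome 17 the running median steps from a stretch with a median of 0.52 to one with a median of -0.52.

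Between the untreated lines 2647 genes passed limma's test, 1312 higher and 1335 lower in P/R cells, of which 112 and 88 by at least 1 on the log2 scale. A single P/R derivative was sampled, so the p-values of both line comparisons measure spread between cultures, not between resistant lines. Differences tied to resistance cannot be told apart from others that this derivative acquired. The number fell to 1756 without untreated parental replicate 1, and to 1594 and 1661 without untreated P/R replicates 1 and 2. Mitochondrially encoded genes took 4.37% and 4.83% of the summed FPKM in the untreated parental libraries and 5.56% and 5.78% in the untreated P/R libraries, against 4.88% and 4.98% in treated parental and 4.84% and 5.4% in treated P/R libraries.

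The lines were also compared under OTX015, to ask which differences remained in the presence of the drug. PF4 stood at 43.6 ± 0.583 FPKM in P/R and 1.47 ± 0.339 FPKM in parental cells (log2 difference 4.18), and KRT18 at 87.7 ± 0.952 against 13.5 ± 0.46 FPKM. KALRN, which encodes a guanine nucleotide exchange factor, stood at 11.3 ± 0.229 against 1.2 ± 0.662 FPKM, NNMT at 5.6 ± 0.524 against 0.169 ± 0.0361 FPKM and C1orf116 at 11.2 ± 0.794 against 1.38 ± 0.186 FPKM. GALNS, APOE, C16orf45 and KIT were at 0.12, 0.131, 0.128 and 0.139 of the parental level, and H2AFJ, at 5.86 and 5.68 FPKM in the parental replicates, was listed at 0 in the P/R ones. Megakaryocyte genes were higher in 18 of 21 cases, lower in 1 and did not pass in 2; adjusted over the list alone 18 were higher and 2 lower (median 0.81, adjusted p = 1.54e-13; adjusted p = 0.2 with an estimated correlation). GP6, GP1BA and GP9 were 4.81-, 3.77- and 3.27-fold higher, and PLEK was the lower one. Histone genes were higher in 14 of 19 cases, lower in 2 and did not pass in 3, the same as adjusted over the list alone (median 0.70, adjusted p = 7.78e-09; adjusted p = 0.2 with an estimated correlation). HIST1H1C stood at 514 ± 2 against 102 ± 3.94 FPKM, HIST1H2BK, HIST2H2AA3 and HIST1H2BD were 4.45-, 2.49- and 2.22-fold higher, and HIST2H2BF and H2AFJ lower.

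**Figure D5:**
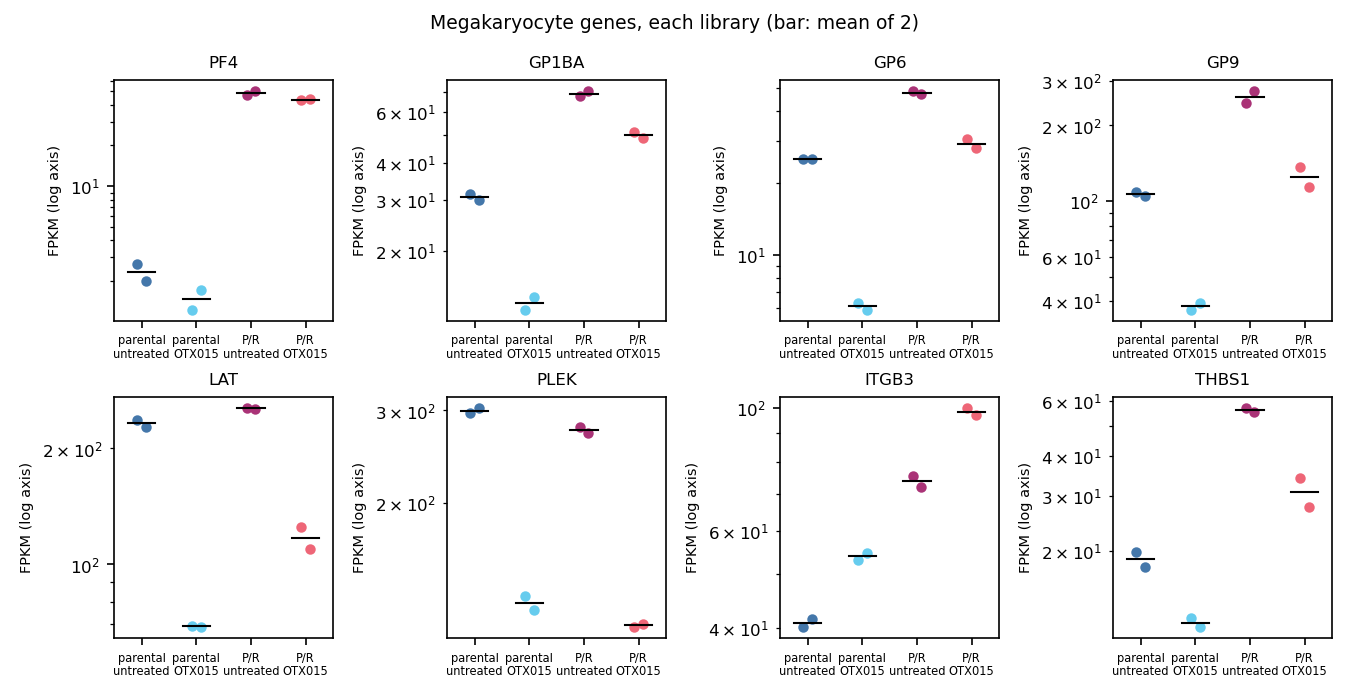
FPKM of 8 megakaryocyte genes in each library on a log axis, with 1 point per library and a bar at the mean of the 2 replicates of each group. GP6 means are 25.3 and 6.08 FPKM in parental and 47.8 and 29.2 FPKM in P/R cells, untreated and treated.

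All 4 tested members of the epithelial and stromal list were higher under OTX015 too, also adjusted over the list alone (median 1.46, adjusted p = 1.64e-05; adjusted p = 0.274 with an estimated correlation). KRT8 was 5.5-fold and PECAM1 1.81-fold higher, and CDH5, at 0.643 against 0.179 FPKM, lost its call with a pseudocount of 5, without either treated parental replicate or without treated P/R replicate 1. Monocyte and granulocyte genes were higher in 6 of 13 cases and did not pass in 7, with 7 adjusted over the list alone (median 0.26, adjusted p = 0.00641; adjusted p = 0.218 with an estimated correlation). LST1, CD68, CD4 and CEBPD were 1.69-, 1.96-, 1.45- and 1.82-fold higher; the list's call was lost without the filter on low values, at an adjusted p of 0.138, and that of CEBPD without treated parental replicate 1 or treated P/R replicate 1. The ribosomal protein, lymphocyte, S phase and MYC target lists, called in untreated cells, had adjusted p = 0.0815, 0.138, 0.138 and 0.224 here. Median and mean, or either of them and the test, differed in sign for 9 lists that were not called: CDK inhibitors and p53 targets, the study axis, BET inhibitor-sensitive genes, WNT components, stem and progenitor, erythroid, heat shock, reference and drug efflux genes.

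Under OTX015 2747 genes passed limma's test between the lines, 1432 higher and 1315 lower in P/R cells, of which 128 and 65 by at least 1 on the log2 scale. The number was 1758 without treated parental replicate 1. The 2 line comparisons share no library; their fold changes correlated across genes at r = 0.81, with 942 genes higher in both, against 166.9 for independent lists, 849 lower in both, against 156, and 6 called in opposite directions.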

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

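The test against the slope over all genes was chosen only after the differences had been seen, as was the use of planned settings to weigh explanations; the test of each difference in response was planned.

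Beyond GP6, GP1BA and LAT, given with the megakaryocyte genes below, the genes whose OTX015 response differed between the lines by limma's test of the difference itself were as follows. CSF1 differed by 1.08 on the log2 scale, with an adjusted p between 0.00914 and 0.211 over 15 other settings. NR5A1 differed by 0.689, with an adjusted p between 0.00914 and 0.176. TRIM15 differed by 0.561 and DMTN by 0.541, both as smaller falls in P/R cells. HDC differed by -0.62, with an adjusted p between 0.0219 and 0.211. MARCKSL1 differed by -0.764, with an adjusted p between 0.00161 and 0.0831. The list of BET proteins and P-TEFb differed by a median of -0.121, with an adjusted p between 0.00142 and 0.315, and of 0.223 after the parental response was scaled by the slope over all genes. The lymphocyte list differed by a median of 0.397, with an adjusted p between 4.41e-06 and 0.0359 over 14 other settings, the highest with a pseudocount of 0.1, and of 0.00462 after that scaling. For its member CD2 the difference comes from the pseudocount at unequal low levels, and it was 0.0941 with a pseudocount of 0.1. After the scaling, histone and S phase genes lay higher than scaled (camera adjusted p = 5.95e-07 and 0.0404, medians 0.193 and 0.04). ATF4 and stem and progenitor genes lay lower (camera adjusted p = 0.0404 and 0.0475, medians -0.0548 and -0.118). The scaled response was tested only at the preset correlation, so whether it was weaker by 1 factor in all groups of genes stays open.

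The smaller fall of megakaryocyte genes in P/R cells, with a median difference of 0.123, includes GP6 (1.2, adjusted p between 0.00161 and 0.05 over 15 other settings), GP1BA (0.687, between 0.0244 and 0.224) and LAT (0.623, between 0.0123 and 0.206). The part of the pseudocount stays open, since a pseudocount of 0.1 gave a larger median difference of 0.224 whereas one of 5 gave 0.0589 and ended the call (adjusted p = 0.102). A generally weaker response in P/R cells stays open for this list: after the parental response was scaled by the slope over all genes, the list had a camera p of 0.0258 unadjusted and 0.0957 adjusted over 26 lists, with a median of 0.0877, and the adjusted value was made the criterion after the unadjusted one had been seen. A single library may carry much of the difference at the level of the list, since without P/R OTX015 replicate 1 the median was 0.0344 and the adjusted p 0.113, but other libraries moved it too, to 0.0683 and 0.078 without replicate 1 of the treated and untreated parental cells and to 0.212 without P/R OTX015 replicate 2. A change of lineage state in P/R cells, which the design could hold, was not tested.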

How the results depend on the processing

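The crossed replicate block and the removal of a local median along the chromosome were chosen only after the results were seen; the other settings were planned. Of 233 named results, 211 kept their direction and their side of the threshold in all settings run, 22 did not in at least 1 of the 18 settings, and 0 reversed; the cause was not tested. Requiring a log2 fold of at least 1 left 486 and 314 genes for OTX015 in parental and P/R cells, 200 and 193 for the lines untreated and treated, and 2 for the difference in response, by construction. That difference had 4 genes with a pseudocount of 0.1, 29 with 5, 4 without the filter, 3 without the variance trend and 2 with the replicate block. Leaving out 1 library gave 1594 to 2684 genes between the untreated lines, 1758 to 2624 between the treated lines and 0 to 8 for the difference in response, with fewer samples and the lone replicate assumed to vary like the other groups. The correlation of the OTX015 responses was 0.863 with a pseudocount of 0.1, 0.909 with 5, 0.874 without the filter, 0.923 at a mean of at least 5 FPKM and 0.867 to 0.88 without 1 library. With an estimated inter-gene correlation 1, 1, 0, 0 and 0 lists were called in the 5 comparisons, in the order of the design. At a mean of at least 5 FPKM, 5 lists were called between the untreated lines, and 1 for the difference in response, as also without the filter; leaving out 1 library gave 1 to 3 there.

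The labels number the replicates but say that cells were treated independently. Deviations of same-numbered libraries correlated at 0.014, 0.007, 0.104, -0.005, -0.12 and 0.014 across genes. The values farthest from 0 set treated P/R cells against untreated (0.104) and treated (-0.12) parental cells. Some structure shared between these libraries, also with the numbers crossed, cannot be excluded, and its source was not tested. With the replicate block 5565, 4875, 2517 and 2555 genes were called in the first 4 comparisons. With the crossed block 2548 were called between the treated lines. With the local median removed, 2026 genes (1847 of them shared with the fit as designed) were called between the untreated and 2092 (1906 shared) between the treated lines. Median centring moved the median fold change by at most 0.000161. Depth is unknown, so what it limits cannot be stated.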

Other observations

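All tests in this part, and the lists behind its gene groups, were chosen only after the results were seen.

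Mast cell, basophil and eosinophil genes were lower in untreated P/R cells in 11 of 18 cases, higher in 2 and did not pass in 5; adjusted over the list alone 12 were lower and 3 higher (median log2 difference -0.75, camera adjusted p = 3.04e-05 over 4 lists). The call held with an estimated correlation in untreated cells (adjusted p = 0.0407) but not under OTX015 (adjusted p = 0.0676), and the list was drawn up after CPA3, PRG2 and KIT had been seen to be lower. HDC, which makes histamine, stood at 255 ± 11.2 against 403 ± 31.6 FPKM (mean ± SD, n = 2). CSF2RB, the shared receptor chain for interleukins 3 and 5, stood at 16.7 ± 0.467 against 29.7 ± 1.67 FPKM. LTC4S, of leukotriene synthesis, was higher, at 21.3 ± 0.754 against 10.9 ± 0.297 FPKM. FCER1A, at 133 ± 0.499 against 136 ± 5.09 FPKM, and GATA2, at 267 ± 6.73 against 292 ± 5.66 FPKM, did not pass. Some lower members were low in both lines, such as TPSAB1 at 0.477 against 1.61 FPKM and IL1RL1 at 0.3 against 1.12 FPKM. The list has 29 members, of which 18 were tested, and IL1RL1 passed the filter only through parental libraries. Of 44 cancer-testis antigen genes, 9 were tested. Of these, 7 were higher and 2 did not pass, and adjusted over the list alone 7 were higher and 1 lower (median 2.07, camera adjusted p = 9.05e-07, and 0.122 with an estimated correlation). MAGEA2, MAGEA2B and MAGEA12 were below 1 FPKM in both parental groups and passed the filter only through P/R libraries. The share of higher members is thus in part set by the filter. MAGEA3, a near-identical copy of MAGEA6, stood at 16.2 ± 1.31 against 2.98 ± 0.429 FPKM, MAGEA12 at 3.01 ± 0.042 against 0.253 ± 0.021 FPKM and PRAME at 65.6 ± 0.218 against 46.6 ± 0.648 FPKM. MAGEA1, at 45.3 ± 0.88 against 50.7 ± 0.659 FPKM, did not pass.

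HLA and antigen presentation genes were lower in 5 of 16 cases and did not pass in 11, with 7 adjusted over the list alone (median -0.14, adjusted p = 0.00359; adjusted p = 0.14 with an estimated correlation); HLA-DPA1 stood at 10 ± 0.48 against 16.5 ± 1.62 FPKM and HLA-B at 122 ± 2.5 against 148 ± 0.882 FPKM. Mitochondrially encoded genes were higher in untreated P/R cells in 10 of 13 cases and did not pass in 3, with 11 adjusted over the list alone (median 0.45, adjusted p = 9.05e-07; adjusted p = 0.152 with an estimated correlation). Their response to OTX015 was called different between the lines as a list only at the preset correlation of 0.01 (median difference -0.33, camera adjusted p = 1.6e-09). Of the 13 members 0 passed, and 8 were lower adjusted over the list alone. With the estimated correlation of 0.678 the camera adjusted p was 0.374. Members this strongly correlated are not separate measurements, so the p-values of this list at the preset correlation overstate the evidence in both comparisons. Single genes beyond these lists also stood apart between the untreated lines: ALDH1A1, an aldehyde dehydrogenase, at 15.3 ± 1.16 against 64.8 FPKM, TFRC, the transferrin receptor, at 102 ± 3.02 against 244 ± 22.2 FPKM, and GSTP1, a glutathione transferase, at 209 ± 0.316 against 104.8 ± 4.95 FPKM. ALDH1A1 and GSTP1, which differed in opposite directions, belong to the planned drug efflux and metabolism list, and TFRC to the erythroid list among others. None of these planned lists was called between the untreated lines.

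The 4 stretches on chromosomes 3, 14 and 17 are not explained by a chance order of the fold changes. In 100 shuffles among positions the running median reached at most 0.186, against 0.638 observed, with 0 runs. The end rule of the running median had been changed after artefacts in shuffled data. Shuffling also breaks up neighbours that vary together, which can form runs by themselves. Under OTX015 in parental cells, for example, a run of 67 genes on chromosome 6 held 48 histone genes. For quantile normalization, genes elsewhere at matched levels had a median of -1.21e-05, with a central range of -0.0184 to 0.0179 over 1000 draws, against 0.506 in the stretches. This test cannot decide the part of the normalization. The matched genes were drawn only from outside the stretches and given the signs of stretches in both directions, so a shift that depends on level would largely cancel. A change in DNA copy number in the P/R line is a candidate explanation: in the OTX015-treated libraries, which are separate from the untreated ones, 95.4% of the 568 genes lay on the same side. Neither copy number nor ploidy was measured, and regional control of chromatin would give the same test result. Copy number remains a hypothesis drawn from these same data.

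KRT8 and KRT18 were higher in P/R cells in both line comparisons. The other 13 markers looked at had failed the filter on low values, so their low level was largely known before this test was chosen. Their highest value in any P/R library was 0.764 FPKM, for COL1A1, where an increase of KRT18 by 60.0 FPKM would call for far more. This argues against epithelial or stromal cells that express these markers. It does not cover endothelial cells, since PECAM1 and CDH5 were left out and were higher in P/R cells. PECAM1 read 13.4 and 13.5 FPKM in the untreated P/R libraries, against 10.6 and 10.1 FPKM in the untreated parental ones. A broad shift of the chromosome neighbourhood is argued against as well, since the running median over 41 tested genes was -0.056 at KRT8 and KRT18. Such a median cannot respond to a change limited to a few genes. Both keratin genes lie on chromosome 12 with the same local median, so a change confined to them and close neighbours stays open. Reads shared with keratin pseudogenes were not analysed here, and a change within the leukaemia cells was not tested.

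Whether untreated P/R cells resemble OTX015-treated parental cells was asked with the covariance across genes of the parental OTX015 response and the untreated line difference, which share the untreated parental libraries. The observed covariance was 0.00685 (r = 0.0439). Unchanged groups against the shared controls gave a mean of 0.00593 and a range of 0.00545 to 0.00663 over 100 simulations with the moderated variances of the fit, and a mean of 0.00874 and a range of 0.0067 to 0.0121 with the variances of the untreated parental pair, a version written after the former had been run. The observed value lies above the first range, although an earlier draw of those simulations had reached past it, and inside the second, so a small resemblance and the effect of the shared controls cannot be told apart. Genes higher in both contrasts numbered 371, against 337 for independent lists, genes lower in both 466, against 329, and genes in opposite directions 753, against 667. Shared controls could raise only the same-direction counts, and these expectations take no account of them.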
